A study of Mus musculus with 19 samples.

How the data were processed

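The series holds RNA sequencing profiles in cells from the bone marrow of C57BL/6 mice. Per the labels, mice were spun in a centrifuge at 15 G in sessions of 15 min, or served as controls listed at 0 G, and the intervention lasted about 1 or 3 weeks. Bone marrow-derived macrophages (BMDM) are macrophages grown from marrow precursors with the growth factor M-CSF, and bone marrow mesenchymal stem cells (BMSC) are the adherent stromal cells of marrow. The growth protocol in the labels describes macrophage culture for both cell types. Total RNA was taken with Trizol and had an integrity number above 8.0, per the labels' protocols.

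The deposited values are raw gene counts, 1 column per library and 1 line per gene symbol, as deposited by the authors. The reads were aligned with HISAT2 2.0.4 to mm10, per the submitters' processing notes. The counting program, its gene annotation and its strand setting are not given in the sources used here. Genes that overlap, antisense genes and near-identical copies such as ribosomal protein pseudogenes are therefore uncertain. The table lists 46095 symbols, of which 33980 matched the GENCODE mouse annotation of the mm10 assembly by symbol and 525 by an older symbol. That match was used only for positions, exonic length and GC content. Totals ran from 16.32 to 33.02 M counts (1e6) per library, so a count of 3, taken as the floor for a gene at 0, was worth 0.0909 to 0.184 CPM (counts per 1e6 counts). Intervals and floors cover counting error only.

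The 19 libraries were assigned to 8 groups by their titles and labels. Controls of the 1 week set carry no duration in the labels and were taken as the partners of the 1 week animals because their names follow the same pattern. Nothing states whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Replicates of a group differed by 4.3 to 97.9 times the counting variance in a chi-square comparison of genes with at least 20 counts, so no library was treated as a repeat of another.

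Gene counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test after TMM scaling and the filterByExpr filter, with 1 coefficient per group and no further covariate. BMDM and BMSC libraries were fitted separately, with 13842 genes and 5 residual degrees of freedom in BMDM and 15289 genes and 6 in BMSC. Differences between cell types came from a fit of all 19 libraries with 15550 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The contrasts were hypergravity minus control in each set, the mean of both sets, the difference between sets (3 weeks minus 1 week) and the difference between cell types (BMDM minus BMSC). All adjusted p-values for genes are from edgeR unless another tool is named. CPM are given as mean ± SD per raw library total, whereas log2 fold changes (± SE) follow TMM scaling. The TMM factors of the 1 week hypergravity BMDM libraries were 0.853 and 0.868, so CPM ratios there lie below the fitted folds.

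In all, 33 gene lists covering the unfolded protein response, osteoclasts and their regulators, stromal and matrix genes, inflammation, growth, metabolism and markers of other marrow cells were fixed before the data were examined, together with the grouping, tests and naming rule. Lists with at least 4 tested genes entered camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and the 180 tests formed a common adjustment. No list call held with an estimated correlation. Fry, which asks whether the genes of a list move one way and compares them with no other genes, was run as an alternative; it kept 8 of 8, 3 of 12 and 7 of 8 list calls in BMDM at 1 week, at 3 weeks and over both sets, and 0 of 5, 0 of 8 and 0 of 8 in BMSC. Counts "adjusted over the list alone" refer to edgeR p-values adjusted within a list. Erythroid markers had too few tested genes in both cell types, as did B cell, T and NK cell and megakaryocyte markers in BMDM and skeletal muscle markers in BMSC. Genes were named by rule: the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM, no overlap between arms and an established symbol (the 5 with the smallest p where fewer than 5 passed), a fixed set of unfolded protein response, osteoclast and stromal genes, and up to 4 members of each list with the smallest p. Some results for single genes that the rule names were left out because they are withheld for evaluation. Genes named outside this rule are said to be chosen after their values were seen.

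Alternatives comprised DESeq2 1.42.0, its size factors in edgeR, no count filter, a filter at 1 CPM, a log2 change of at least 1, the replicate number as a block, only the groups compared, a fit of all libraries, and omission of each library. Scaling by library size alone, removal of a trend on exonic length or GC content, and a matrix gene covariate were added after seeing the data. On simulated counts with 100 genes changed at each fold, edgeR recovered 30% of 1.5-fold and 82% of 3-fold changes for the 1 week BMDM comparison over 13520 genes, and 12% and 78% for 3 weeks. The corresponding shares for BMSC were 18% and 71% at 1 week over 14985 genes and 5% and 72% at 3 weeks over 14962 genes. False calls numbered 6 of 118, 4 of 94, 4 of 93 and 2 of 79 with edgeR, and 19 of 148, 21 of 125, 33 of 145 and 20 of 108 with DESeq2. The simulated counts were drawn independently for each gene around its mean over the libraries of the cell type. They carried no shift shared across genes, such as a trend on exonic length, so these shares need not hold for the real libraries. A stretch of the major histocompatibility region on chromosome 17 (mm10, 34956436 to 35128855) had all 20 of its protein-coding genes below 1 CPM, and Tnf, Aif1, Clic1, Bag6, Prrc2a and Ddx39b, in and next to it, were listed at 0 in all 19 libraries. Windows of 20 genes around it, from 34143307 to 34935953 and from 35128997 to 35516824, had 18, 19 and 19 genes below 1 CPM. The next window out, from 33875659 to 34139101, had 14. The list members Tnf, Aif1, Hspa1a, Hspa1b and Atf6b lie in these windows and could not be assessed. H2-Aa, H2-Ab1, H2-Eb1 and Neu1, also there, averaged 1.44, 0.882, 0.816 and 5.82 CPM, so their counts may be incomplete.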

Results

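RNA was sequenced from BMDM and BMSC of hypergravity-exposed and control mice, under a series title that links hypergravity to osteoclast formation and to the unfolded protein response (UPR), the reaction of cells to misfolded protein in the endoplasmic reticulum (ER). In BMDM, 3 controls and 2 hypergravity libraries made up the 1 week set, and 2 of each made up the 3 week set. In BMSC there were 3 of each at 1 week and 2 of each at 3 weeks. Library totals, in M counts (1e6), ranged from 18.35 to 33.02 in the 1 week BMDM set and from 17.21 to 22.71 in the 3 week BMDM set. In BMSC they ranged from 17.6 to 28.9 at 1 week and from 16.32 to 21.63 at 3 weeks.

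Libraries of both cell types carried macrophage transcripts at high level. Lyz2, the lysozyme of macrophages and granulocytes, averaged 18430 ± 3219 CPM in BMDM (SD, n = 9) and 20050 ± 1535 CPM in BMSC (n = 10), where it was the most abundant gene on average. The M-CSF receptor gene Csf1r stood at 2194 ± 311 CPM in BMDM and 1231 ± 205 CPM in BMSC, and Cd68 at 1494 ± 269 and 1064 ± 180 CPM. Stromal genes set the BMSC libraries apart, with the collagen gene Col1a1 (chromosome 11, 94936224 to 94953042, mm10) at 1908 ± 1078 CPM against 7.77 ± 4.95 CPM in BMDM and the marrow stromal chemokine gene Cxcl12 at 481 ± 334 against 0.594 ± 0.502 CPM. Col1a1 ranged from 546 to 3582 CPM among the 10 BMSC libraries. Markers of further marrow cells were also present in BMSC, including the neutrophil gene S100a9 at 669 ± 183 CPM (68.9 ± 60.5 in BMDM) and the endothelial gene Cdh5 at 47.6 ± 34.4 CPM (0.647 ± 0.426 in BMDM).

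**Figure D1:**
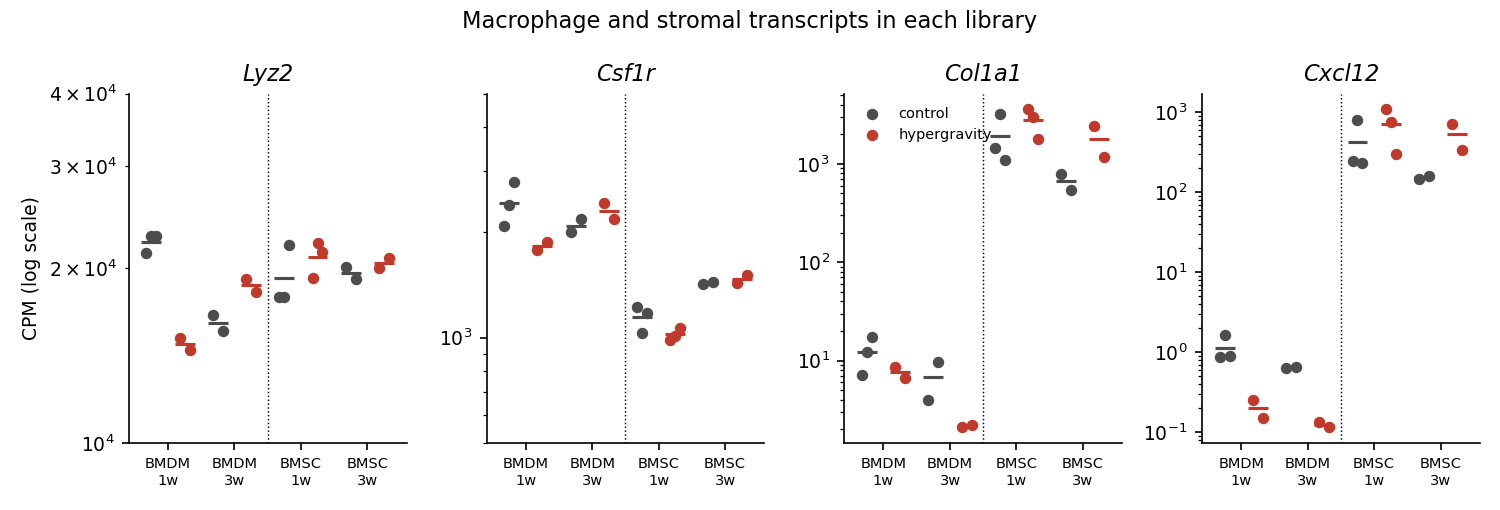
CPM of Lyz2, Csf1r, Col1a1 and Cxcl12 on a log axis, with 1 point per library (controls grey, hypergravity red) and a bar at the mean of each of the 8 groups. Lyz2 and Csf1r were abundant in both cell types, whereas Col1a1 averaged 1908 CPM in BMSC and 7.77 CPM in BMDM.

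The first question was how macrophages from mice with 1 week of hypergravity differed from those of controls. They showed a broad rise of inflammatory genes. Saa3, an acute phase protein gene (chromosome 7, 46711998 to 46715700), rose from 3.31 ± 0.95 CPM (n = 3) to 17540 ± 462 CPM (n = 2), a log2 fold change of 12.59 ± 0.25 (SE, edgeR adjusted p = 5.49e-10). The prostaglandin synthase gene Ptgs2 rose from 4.13 ± 2.49 to 4376 ± 127 CPM (10.37 ± 0.40, adjusted p = 1.99e-08). The chemokine gene Cxcl2 (chromosome 5, 90903871 to 90905938) rose from 4.42 ± 0.87 to 2892 ± 65.6 CPM (9.61 ± 0.18, adjusted p = 5.49e-10). The nitric oxide synthase gene Nos2 rose from 0.311 to 1270 ± 118 CPM (12.33 ± 0.27, adjusted p = 9.17e-10). Csf3 (chromosome 11, 98701263 to 98703629), which encodes the granulocyte growth factor G-CSF, was at 0 in all 3 controls and at 261.3 CPM under hypergravity, at least 6011-fold higher against a floor of 3 counts over the control group. By the same measure Shisa3, Gipr and Lad1 were at least 586.7-fold, 511.6-fold and 426.9-fold higher. Il6 (chromosome 5, 30013114 to 30019981), a cytokine gene, had 3 counts over the controls and 307.2 ± 19.5 CPM under hypergravity, a ratio of 7029 with a 95% counting interval of 2405 to 34090. Il12b, another cytokine gene, went from 0.0731 to 317.7 ± 9.2 CPM.

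Large falls were seen as well. Cd163, a scavenger receptor gene, fell from 25.3 ± 24.0 to 0.211 CPM (log2 -6.50 ± 0.97, edgeR adjusted p = 0.000238). Hpgd, which encodes a prostaglandin-degrading enzyme, fell from 120.1 ± 42.4 to 0.759 ± 0.083 CPM (-7.01 ± 0.40, adjusted p = 2.6e-07) and Slc46a3 from 101.4 ± 14.2 to 1.07 ± 0.16 CPM (-6.27 ± 0.18, adjusted p = 3.17e-09). Slco2b1 (-7.10), Gprc5c (-6.57), Stab2 (-6.15) and Cmbl (-6.10) also fell. Smpd3, Abca6 and Mpo had so few counts left under hypergravity that ratios of 407.4 (counting interval 112.5 to 3368), 169.3 (57.67 to 822.9) and 168.3 were obtained. In all, edgeR called 8494 of 13842 genes, 4225 higher and 4269 lower, with 9035 genes at an unadjusted p below 0.05. The higher share was 49.7%, and 34.7% when libraries were scaled by total alone, which moved the median gene from -0.03 to -0.29 on the log2 scale. The share of mitochondrially encoded counts was 1.38 ± 0.013% in controls and 0.785 ± 0.001% under hypergravity at 1 week, and 1.59 ± 0.031% and 1.82 ± 0.04% at 3 weeks, differences that were not tested.

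**Figure D2:**
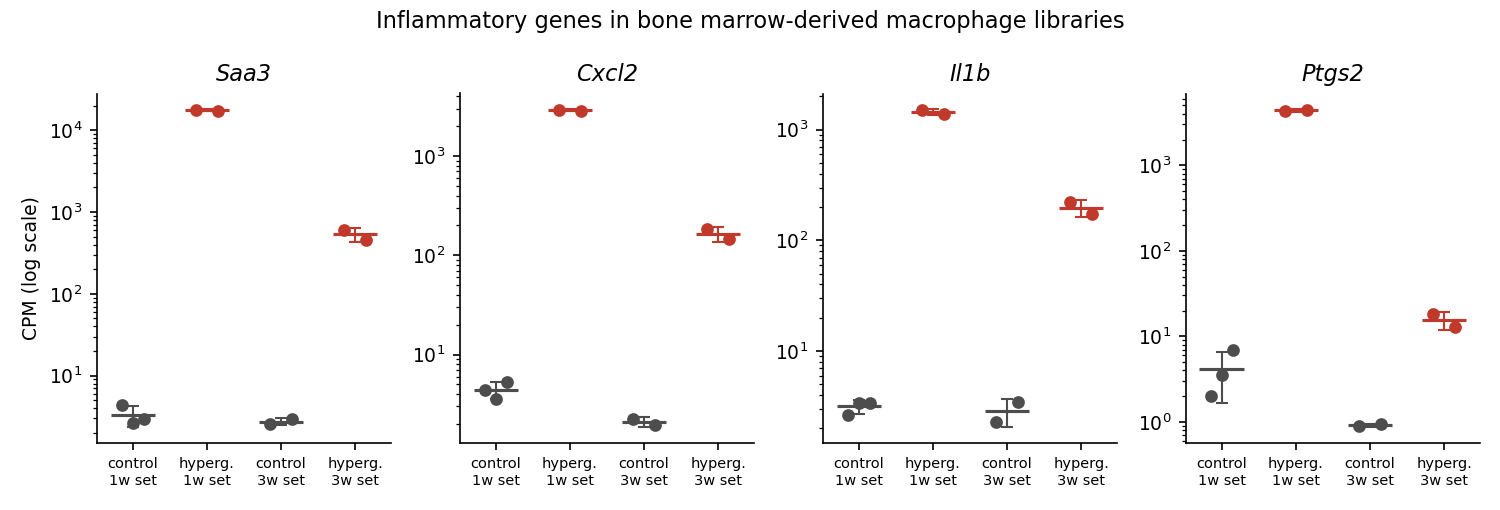
CPM of Saa3, Cxcl2, Il1b and Ptgs2 on a log axis, with 1 point per BMDM library, a long bar at each group mean and a thin bar of 1 SD. Saa3 averaged 17540 CPM in the 1 week and 532.7 CPM in the 3 week hypergravity libraries, against 3.31 and 2.74 CPM in the respective controls.

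Of the UPR genes followed in every comparison, the ER chaperone gene Hspa5 (chromosome 2, 34771970 to 34777547) rose from 855.3 ± 50.3 to 1489 ± 117 CPM in the 1 week BMDM set (log2 1.06 ± 0.09, edgeR adjusted p = 3.84e-06). Atf4 (chromosome 15, 80255184 to 80257541), a transcription factor gene of the PERK arm, rose from 186.2 ± 25.1 to 532.4 ± 32.6 CPM (1.78 ± 0.12, adjusted p = 7.38e-07). Ern1 (chromosome 11, 106394650 to 106487852), the gene of the IRE1 sensor, rose by 1.84 ± 0.35 (adjusted p = 0.00116) and Ddit3, which encodes CHOP, by 0.98 ± 0.12 (adjusted p = 4.68e-05). Eif2ak3, the PERK gene, fell by 0.94 (-0.94 ± 0.14, adjusted p = 0.000255). Xbp1 (chromosome 11, 5520659 to 5525893; 0.13 ± 0.10, adjusted p = 0.265) and Atf6 (-0.11, adjusted p = 0.519) did not pass.

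Targets of ATF4 and CHOP rose as a list, with 21 of 23 members higher and 2 lower, among them the amino acid transporter genes Slc7a11 (28.8 to 683.6 CPM) and Slc3a2 (240.7 to 1200 CPM), Ppp1r15a (30.2 to 327.4 CPM) and Ddit4 (2.16 to 22.7 CPM). The count adjusted over the list alone was the same, and camera gave an adjusted p of 1.63e-06, against an adjusted p of 0.409 with an estimated correlation. ER chaperones and ERAD genes, the list of ATF6 and XBP1 targets, were not called (adjusted p = 0.199): 13 of 24 rose, such as Hyou1 (90.0 to 160.1 CPM) and P4hb (log2 1.04), 4 fell and 7 did not pass. Of the 6 UPR sensors tested, 1 rose and 2 fell (adjusted p = 0.837). Counts adjusted over the list alone equalled these.

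Osteoclast genes moved in both directions. Acp5 (chromosome 9, 22126727 to 22135711), which encodes the osteoclast phosphatase TRAP, rose from 43.6 ± 5.7 to 303.4 ± 17.2 CPM (3.06 ± 0.18, edgeR adjusted p = 3.03e-07). Mmp9 rose by 1.53 ± 0.16 (adjusted p = 1.7e-05), the collagen-degrading cathepsin gene Ctsk by 0.62 ± 0.10 (adjusted p = 0.000458) and Src from 32.8 to 168.8 CPM. The fusion gene Dcstamp (chromosome 15, 39745930 to 39760938) fell from 155.8 ± 31.2 to 20.7 ± 0.89 CPM (-2.66 ± 0.18, adjusted p = 8.75e-07). Falls were also seen for Nfatc1, the transcription factor gene of osteoclast formation (-1.02 ± 0.16, adjusted p = 0.000263), the RANK gene Tnfrsf11a (-1.06 ± 0.11, adjusted p = 1.51e-05) and Trem2 (1033 to 104.9 CPM). In the osteoclast list 9 of 21 members rose, 9 fell and 3 did not pass, also when adjusted over the list alone, and the list was not called (adjusted p = 0.821, median 0.26, mean -0.06). The osteoclast-regulating factors rose, with Il6, Ptgs2, Il1b (3.17 to 1440 CPM) and Csf1 (11.7 to 32.6 CPM) higher and 1 of 5 not passing (adjusted p = 0.0147, and 0.8 with an estimated correlation). Il6, Ptgs2 and Il1b also belong to the list of NF-kB inflammatory genes, so the calls of these lists share genes in every BMDM comparison.

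**Figure D3:**
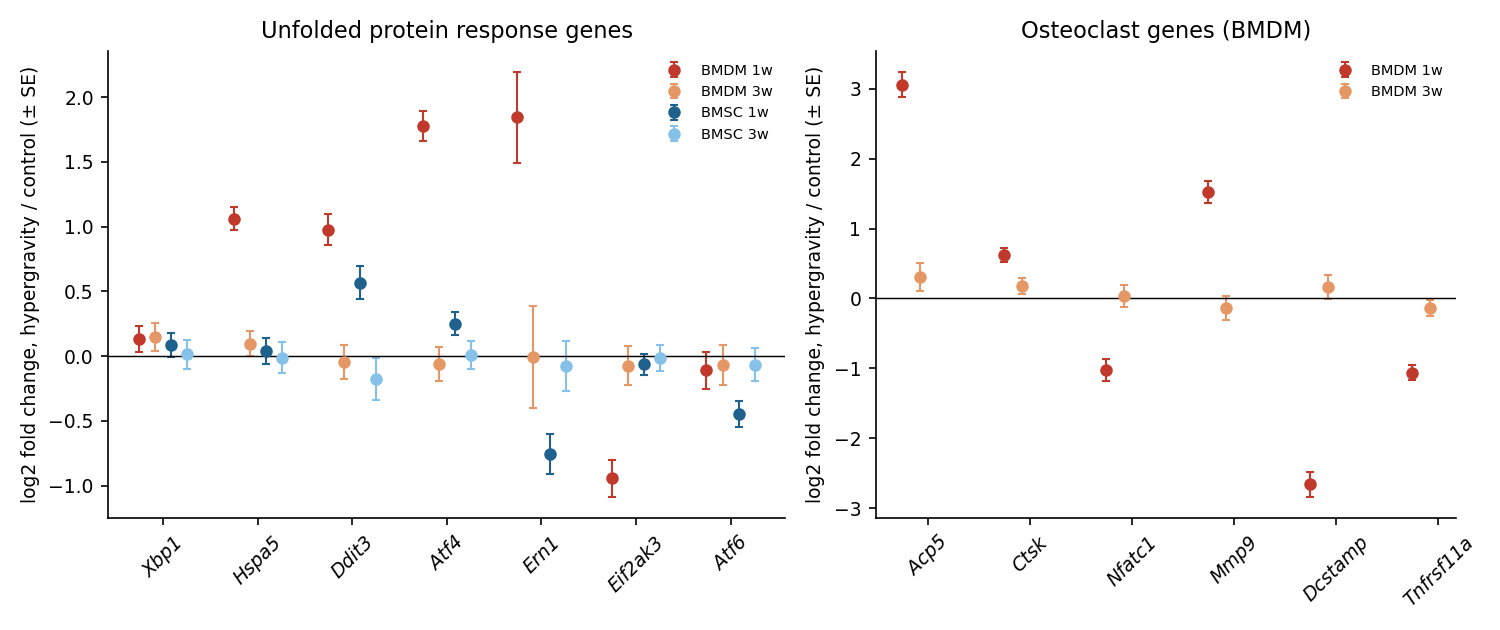
Log2 fold change of hypergravity against control (vertical axis) for UPR genes in the 4 comparisons within a set (left) and for osteoclast genes in both BMDM sets (right), with a bar of 1 SE around each point. In the 1 week BMDM set Atf4 stood at 1.78, Acp5 at 3.06 and Dcstamp at -2.66, whereas 3 week BMDM values lay near 0.

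Further lists changed in the 1 week BMDM set. All 15 NF-kB inflammatory genes tested rose, including Ccl3 (29.9 to 1339 CPM) and Ccl4 (log2 5.07), with a median log2 change of 8.90 that stood with Cxcl3, at 0 in the controls, at its floor (camera adjusted p = 4.71e-11, and 0.456 with an estimated correlation); Tnf was listed at 0 in every library. Interferon-stimulated genes rose in 17 of 18 cases, for example Isg15 (56.5 to 839.4 CPM) and Gbp2 (88.3 to 1398 CPM; adjusted p = 4.01e-07, and 0.8 with an estimated correlation). Hypoxia and glycolysis genes rose in 17 of 19 cases, including the glucose transporter gene Slc2a1 (71.8 to 611.6 CPM) and Egln3 (0.785 to 100.2 CPM), with a further fall when adjusted over the list alone (adjusted p = 4.12e-08, and 0.409 with an estimated correlation). Proliferation genes fell in 19 of 21 cases with none higher, among them Rrm2 (31.4 to 1.05 CPM) and Ccna2 (30.3 to 1.00 CPM; adjusted p = 2.94e-08, and 0.8 with an estimated correlation). Heat shock genes rose in 6 of 7 cases, such as Hsp90aa1 (246.2 to 820.4 CPM; adjusted p = 0.0213, and 0.8 with an estimated correlation). Immediate early genes were higher in 9 cases, with Ier3 at 5.03, and lower in 3 (adjusted p = 0.0469, 0.8 with an estimated correlation, and 0.063 without control replicate 3). Counts adjusted over the list alone were otherwise equal.

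The remaining lists were not called in this set, although single members changed. Macrophage markers rose in 5 and fell in 9 of 16 cases (adjusted p = 0.518), with the scavenger receptor gene Marco going from 4.85 to 913.6 CPM and the mannose receptor gene Mrc1 from 423.8 to 23.6 CPM. Alternatively activated macrophage genes rose in 4 and fell in 3 of 8 cases (adjusted p = 0.627), with Arg1 rising from 0.193 to 17.3 CPM. Lysosomal genes rose in 5 and fell in 9 of 16 cases (6 and 9 adjusted over the list alone, adjusted p = 0.563), and Ctsd went from 15940 to 5877 CPM. Cholesterol synthesis genes rose in 5 and fell in 11 of 19 cases (adjusted p = 0.254), with Dhcr7 falling from 24.8 to 4.77 CPM. Adipocyte genes fell in 5 of 7 cases (adjusted p = 0.112), Pparg from 104.4 to 9.18 CPM, and neutrophil markers in 7 of 11 (adjusted p = 0.0766), Elane with a log2 change of -4.34. Adjusted p was 0.254 for class II and dendritic cell genes (3 of 8 lower; 3 of the 8 lie in the depleted part of chromosome 17, where counts may be incomplete), 0.223 for glucocorticoid-responsive genes (5 of 8 higher, 1 lower) and 0.917 for clock genes (4 of 10 higher, 5 lower). Further values were 0.842 for oxidative phosphorylation (3 of 16 higher, 2 lower; 2 and 0 adjusted over the list alone) and 0.734 for osteoblast genes (1 of 5 higher, 1 lower). It was 0.329 for marrow stromal markers (2 of 12 higher, 5 lower), 0.38 for extracellular matrix (2 of 19 higher, 8 lower), and 0.478 for actin cytoskeleton and YAP targets (3 of 16 higher, 8 lower). Markers of other cells gave 0.679 for endothelial markers (2 of 5 higher, 1 lower), 0.12 for mast cell and basophil markers (3 of 4 lower), 0.827 for skeletal muscle markers (0 of 4 called) and 0.524 for sex-linked genes (1 of 4 lower).

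The next question was the response of macrophages after 3 weeks. A smaller number of inflammatory genes was higher. Saa3 rose from 2.74 ± 0.26 to 532.7 ± 104.7 CPM (n = 2 each; log2 7.64 ± 0.26, edgeR adjusted p = 3.81e-07) and Cxcl2 from 2.10 ± 0.23 to 165.4 ± 27.8 CPM (6.34 ± 0.20, adjusted p = 3.81e-07). Of the interleukin genes, Il1b rose from 2.89 ± 0.82 to 197.6 ± 34.8 CPM (6.13 ± 0.22, adjusted p = 3.81e-07) and Il1a from 0.913 to 45.2 CPM. Acod1, which encodes the itaconate-producing enzyme, rose from 4.47 to 241.9 CPM, and Clec4e from 10.9 to 281.9 CPM. Cxcl1, Cav1 and Tarm1 rose by 5.90, 4.91 and 4.59 on the log2 scale. Il6 was at 0 in both controls and at 9.26 ± 0.85 CPM under hypergravity, at least 126.2-fold higher against a floor of 3 counts over the group (adjusted p = 2.18e-05). Ptgs2 rose from 0.914 to 15.6 CPM (4.13 ± 0.50, adjusted p = 0.00358), a call lost without control replicate 1 (adjusted p = 0.0816) or control replicate 2 (0.0806). Marco rose from 14.9 to 87.1 CPM (adjusted p = 4.76e-05), Slc7a11 from 30.1 to 80.6 CPM and Scd1 from 3.55 to 8.62 CPM (both adjusted p = 0.0295); the last 2 calls were lost on leaving out any of the 4 libraries, with adjusted p between 0.106 and 0.496.

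In total edgeR called 59 of 13842 genes at 3 weeks, all of them higher, and 593 genes had an unadjusted p below 0.05, where 692 would be given by chance. The count was 37 without control replicate 1, 35 without control replicate 2, 37 without hypergravity replicate 1 and 50 without hypergravity replicate 2, and 139 with only these 4 libraries in the fit. Other settings gave lower calls too: 23 of the 139, 62 of 205 with no count filter and 6 of 95 by DESeq2. NF-kB inflammatory genes were higher in 12 of 15 cases and in 14, with 1 lower, when adjusted over the list alone. Their median log2 change was 5.15, or 4.13 with Il6 and Cxcl3 at their floors (camera adjusted p = 1.04e-50, and 0.219 with an estimated correlation). The osteoclast-regulating factors Il6, Il1b and Ptgs2 rose and Csf1 was lower when adjusted over the list alone (11.6 ± 1.5 and 6.62 ± 1.08 CPM; camera adjusted p = 2.94e-08, and 0.409 with an estimated correlation).

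None of the UPR and osteoclast genes followed was called at 3 weeks, each with an edgeR adjusted p of 1. Hspa5 stood at 787.5 ± 25.9 CPM in controls and 820.1 ± 5.5 CPM under hypergravity, Atf4 at 199.9 ± 5.2 and 186.6 ± 4.8, and Xbp1 at 129.8 ± 1.2 and 140.0 ± 1.5. Acp5 stood at 33.6 ± 2.9 and 40.4 ± 12.2, Dcstamp at 127.1 ± 11.4 and 139.0 ± 14.3, and Nfatc1 at 49.5 ± 3.9 and 49.5 ± 3.0 CPM. Camera did not call the UPR sensors (adjusted p = 0.917), the ATF4 and CHOP targets (0.722, with Slc7a11 higher and, adjusted over the list alone, 1 member lower) or the osteoclast genes (0.776, 0 of 21 called). ER chaperones and ERAD genes were called as a list with a median of 0.08 and no called member (adjusted p = 0.0314, 0.8 with an estimated correlation, and 0.245 without hypergravity replicate 1).

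Further lists shifted at 3 weeks, and among the lists named in this paragraph Marco was the only called member. Proliferation genes were lower with a median of -0.33 (camera adjusted p = 1.94e-10), for example Mcm6 at 121.1 ± 3.1 and 88.8 ± 18.1 CPM. Lists of stromal character were lower too: extracellular matrix (median -1.30, adjusted p = 3.05e-08; 1 higher and 7 lower of 19 adjusted over the list alone), actin cytoskeleton and YAP targets (-0.81, 2.94e-08; 5 of 16 lower), marrow stromal markers (-0.70, 9.66e-07; 3 of 12 lower) and osteoblast genes (-0.55, 0.00597; 1 of 5 lower). With an estimated correlation these lists had adjusted p = 0.8, 0.8, 0.409, 0.456 and 0.409 in the order named. Members of the last 4 of these lists included Col1a1 at 6.83 ± 4.03 and 2.16 ± 0.07 CPM and Cxcl12 at 0.642 ± 0.005 and 0.124 ± 0.011 CPM. These are scarce transcripts in BMDM. The Cxcl12 mean under hypergravity lay below the worth of 3 counts in those libraries (0.132 and 0.174 CPM). Interferon-stimulated genes (0.36, adjusted p = 0.00931; 4 of 18 higher adjusted over the list alone), macrophage markers (0.06, 0.044), neutrophil markers (0.35, 0.019) and sex-linked genes (0.39, 0.0314) were higher, with adjusted p = 0.94, 0.8, 0.866 and 0.8 with an estimated correlation. These 4 calls ended on leaving out 1 library, with adjusted p = 0.174 and 0.189 without control replicate 1, 0.88 without hypergravity replicate 1 and 0.988 without control replicate 2. Camera called none of the other 14 lists tested here.

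The sets were then compared directly, as the 3 week minus the 1 week response. Duration cannot be told apart from set in this comparison. The BMDM controls of the sets also differed from each other, with 549 genes called, and the 1 week controls carry no duration label. The difference was negative for Saa3 (-4.95), Ptgs2 (-6.24), Hcar2 (-6.73), Egln3 (-6.53), Inhba (-6.28), Maff (-5.80) and Il12b (-6.15). Of these, only Saa3, Ptgs2 and Il12b were called higher at 3 weeks, with smaller rises than at 1 week. A positive difference was found for Hpgd (6.27), Cd163 (6.08), the chemokine receptor gene Ccr2 (4.84) and Slc46a3 (6.42). No gene was called lower at 3 weeks, so 3 week falls were not shown for these genes. Among UPR and osteoclast genes the responses differed for Hspa5, Atf4, Ddit3, Ern1, Eif2ak3, Acp5, Dcstamp, Nfatc1, Mmp9, Tnfrsf11a and Ctsk, and did not differ detectably for Xbp1 (0.01, adjusted p = 0.957) or Atf6 (0.04, adjusted p = 0.894). Calls were lost for Inhba without control 3 week replicate 2 (adjusted p = 0.056), for Il12b without control 3 week replicate 1 (0.918, with a difference of -2.90), and for Ern1 without 1 week hypergravity replicate 2 (0.0773), 3 week control replicate 1 (0.0556) or either 3 week hypergravity replicate (0.0574 and 0.0654). That of Ctsk was lost without control 1 week replicate 2 (0.0568), either 1 week hypergravity replicate (0.119 and 0.0848), either 3 week control replicate (0.152 and 0.107) or 3 week hypergravity replicate 2 (0.197). EdgeR called 6008 genes, 3037 with the higher value at 3 weeks and 2971 with the lower (50.5% higher, 65.3% with scaling by library size alone). Of the 59 genes called at 3 weeks, 58 were also called higher at 1 week, where 18 would be shared if the calls were independent, and the other was called lower. The difference between sets was called for 48 of the 59, with a smaller rise at 3 weeks for 47. Across the 13842 genes, which are not independent replicates, fold changes of both sets correlated with r = 0.318 and rho = 0.157.

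**Figure D4:**
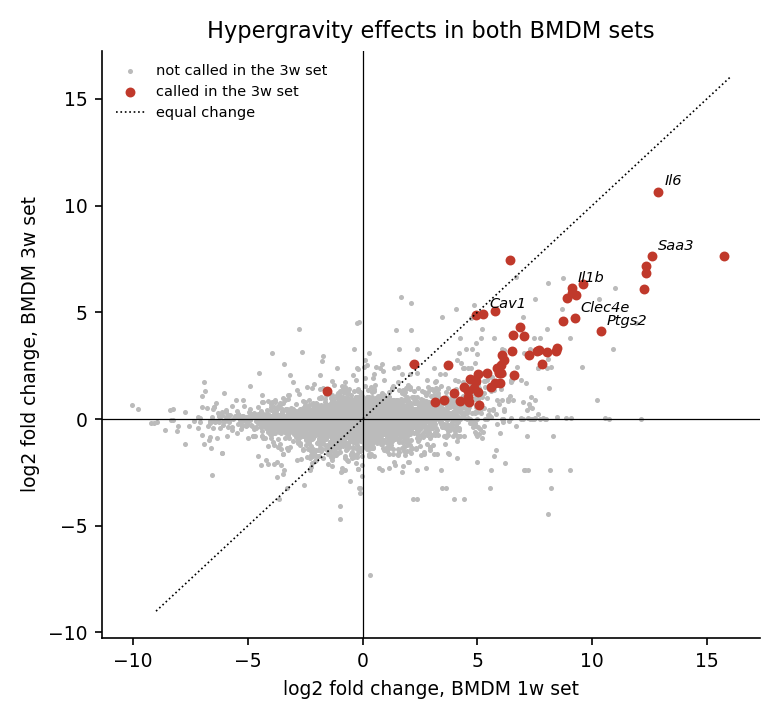
Log2 fold change of each of the 13842 BMDM genes at 1 week (horizontal) and at 3 weeks (vertical), with the 59 genes called at 3 weeks in red and a dotted line of equal change. Marked genes lie mostly below the diagonal, with Saa3 at 12.59 and 7.64.

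Averaged over both sets, the genes with the largest rises were Il6, Csf3, Saa3 (10.11), Nos2 (9.59), Cxcl2 (7.97), Mir155hg (7.66), Il1b (7.62) and Acod1 (7.55), and those with the largest falls Hpgd (-3.88), Cd163 (-3.46), Cmbl (-3.10), Slc46a3 (-3.06) and Ccr2 (-2.87). On this average Hspa5 rose by 0.58, Atf4 by 0.86, Ddit3 by 0.47, Acp5 by 1.69 and Ern1 by 0.92 (edgeR adjusted p = 0.0174). Dcstamp (-1.25) and Eif2ak3 (-0.51) fell. None of these UPR and osteoclast genes was called at 3 weeks, and the response of each differed between the sets. Their averages therefore do not show a change at both durations. The call of Ern1 was lost without 1 week hypergravity replicate 2 (adjusted p = 0.0756), 3 week control replicate 1 (0.0521), 3 week control replicate 2 (0.0642) or 3 week hypergravity replicate 1 (0.0582). EdgeR called 6307 genes, 3085 higher and 3222 lower (48.9% higher, 31.1% with scaling by library size alone). Among the lists called over both sets, ATF4 and CHOP targets, hypoxia and glycolysis genes and heat shock genes were not called at 3 weeks. Their 3 week medians were -0.025, 0.012 and 0.047 in that order. ATF4 and CHOP targets (18 of 23 higher, 1 lower; camera adjusted p = 1.63e-06, and 0.409 with an estimated correlation), NF-kB inflammatory genes (15 of 15; 1.13e-14, and 0.409) and hypoxia and glycolysis genes (17 of 19; 1.65e-08, and 0.409) rose. So did interferon-stimulated genes (17 of 18; adjusted p = 1.77e-07), osteoclast-regulating factors (3 of 5, and 4 adjusted over the list alone; 0.00436) and heat shock genes (5 of 7; 0.0164), while proliferation genes fell (20 of 21; 9.18e-10), each with adjusted p = 0.8 with an estimated correlation. Extracellular matrix genes were lower (2 higher and 9 lower of 19; adjusted p = 0.0469, 0.94 with an estimated correlation, and 0.149 without control 1 week replicate 3).

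For BMSC the 1 week comparison showed modest falls of many genes and rises of a few. Ago2 (chromosome 15, 73095844 to 73184935), which encodes the Argonaute protein of small RNA silencing, fell from 128.9 ± 1.8 to 52.2 ± 12.9 CPM (n = 3 each; log2 -1.35 ± 0.15, edgeR adjusted p = 0.00903). Tmem245 fell from 50.7 ± 2.8 to 19.6 ± 4.3 CPM (-1.40 ± 0.15, adjusted p = 0.00903) and the aminopeptidase gene Lnpep from 121.4 ± 28.9 to 45.7 ± 10.5 CPM (-1.44 ± 0.18, adjusted p = 0.00949). The glutathione transferase gene Gstp1 (chromosome 19, 4035407 to 4037985) had the largest fall, from 21.4 ± 2.7 to 1.83 ± 0.82 CPM (-3.61 ± 0.62, adjusted p = 0.0194), with the caution that close paralogs can share its reads. Zbed6, Lmbrd2, Uhmk1, Kcna2, Zfp369 and Xylt1 fell, with log2 changes from -1.31 to -1.48. The ribosomal protein gene Rpl14 rose from 81.5 ± 4.2 to 133.7 ± 5.8 CPM (0.68 ± 0.08, adjusted p = 0.00949), and Rpl32, Rpl22l1 and Rps21 by 0.79, 0.76 and 0.66. Rps3a3, Rpl6l and Rpl36a-ps2 (0.73, 0.66 and 0.58) are near-identical copies of ribosomal protein genes whose counts are uncertain. Ribosomal protein genes took 1.72 ± 0.11% of the counts in controls and 2.24 ± 0.07% under hypergravity.

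EdgeR called 416 of 15289 genes, 38 higher and 378 lower, with 2821 at an unadjusted p below 0.05 where chance gives 764. The share called higher was 9.1%, 23.8% of 282 calls with scaling by library size alone and 21.7% of 884 by DESeq2. It was 38% of 1313 with no count filter and 41.4% of 2493 with a matrix gene covariate, chosen after seeing the data. EdgeR called 0 genes with only these 6 libraries in the fit (2117 at an unadjusted p below 0.05), 2 in a fit of all 19 libraries and 37 with the length trend of each library removed, also chosen after seeing the data. Of the 38 genes called higher, 13 had ribosomal protein symbols, as had 172 of the 15289 tested genes, and no test of enrichment was run. Long genes were lower and short genes higher: the median exonic length was 1382 bp among higher, 10211 bp among lower and 4179 bp among all tested genes with a length. Calls were lost for every gene without control replicate 1 or without hypergravity replicate 2, each of which left 0. The count was 1109 without control replicate 3, 255 without hypergravity replicate 1 and 169 without hypergravity replicate 3.

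**Figure D5:**
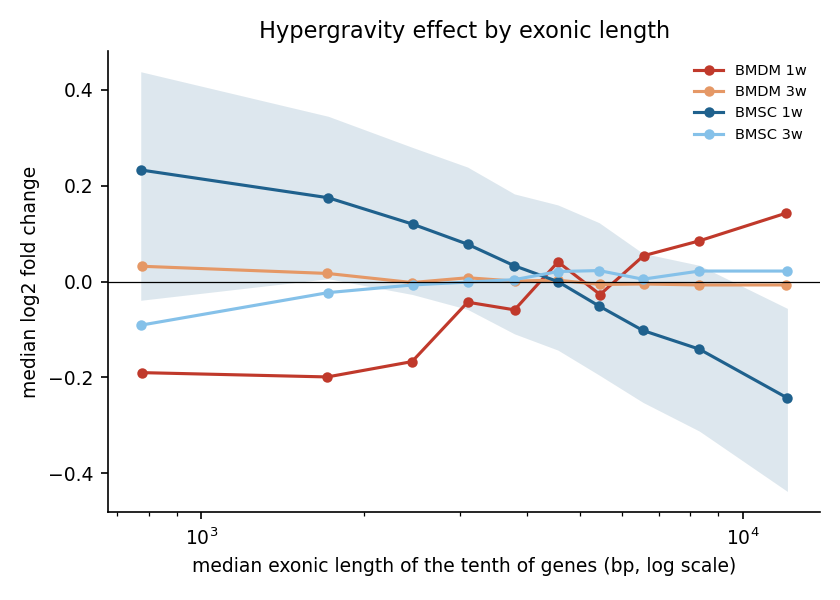
Median log2 fold change of hypergravity against control in 10 equal bins of tested genes ordered by exonic length (horizontal axis, median length in bp on a log scale) for the 4 comparisons within a set, with a band from the lower to the upper quartile of genes for the 1 week BMSC set. The medians fall with length in the 1 week BMSC set, where Spearman's rho across genes was -0.414, against 0.078, -0.069 and 0.108 in the other comparisons.

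Among UPR genes in this set, Ddit3 rose from 18.1 ± 3.0 to 27.4 ± 5.9 CPM (0.57 ± 0.13, edgeR adjusted p = 0.049), whereas Ern1 fell from 40.3 ± 2.2 to 24.4 ± 5.8 CPM (-0.76 ± 0.16, adjusted p = 0.0342) and Atf6 from 154.1 ± 5.5 to 115.9 ± 7.3 CPM (-0.45 ± 0.10, adjusted p = 0.0482), and none of the 3 calls stood without control replicate 1, where no gene was called. With the length trend removed these changes became 0.42 for Ddit3, -0.62 for Ern1 and -0.28 for Atf6, with adjusted p = 0.309, 0.134 and 0.349, and the call of Ddit4 ended too (0.216). Hspa5 (0.04, adjusted p = 0.865), Xbp1 (0.09, 0.661), Atf4 (0.25, 0.164) and Eif2ak3 (-0.06) were not called. ATF4 and CHOP targets rose as a list, with Ddit3 and Ddit4 (39.1 to 56.7 CPM) called, 3 higher and 1 lower adjusted over the list alone, and a median of 0.39 (camera adjusted p = 0.000215, and 0.8 with an estimated correlation). UPR sensors (adjusted p = 0.136; 2 of 6 lower) and ER chaperones and ERAD genes (0.343; 0 of 25 called, 1 higher and 1 lower adjusted over the list alone) were not called.

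Of the stromal genes followed in this set, none was called. Col1a1 stood at 1926 ± 1124 CPM in controls and 2783 ± 916 CPM under hypergravity (0.52, edgeR adjusted p = 0.508). Sp7, an osteoblast transcription factor gene, stood at 0.919 ± 0.437 and 2.28 ± 0.75 CPM (1.29, 0.106), and Alpl at 6.66 ± 2.11 and 10.8 ± 3.2 CPM (0.68, 0.308). The RANKL gene Tnfsf11 stood at 2.90 ± 2.33 and 4.71 ± 1.17 CPM (0.70, 0.488) and Csf1 at 127.3 ± 41.7 and 171.6 ± 42.7 CPM (0.41, 0.382). As lists, osteoblast genes (median 0.60; camera adjusted p = 0.0213, 0.8 with an estimated correlation, and 0.164 without control replicate 3), extracellular matrix (0.34; 0.0371, 0.94 with an estimated correlation, and 0.488 without control replicate 3) and oxidative phosphorylation (0.24; 0.00276, 0.871 with an estimated correlation, and 0.0734 without control replicate 2) were higher with no called member. Neutrophil markers were lower (-0.39; adjusted p = 0.0476, 0.917 with an estimated correlation, and 0.546 without hypergravity replicate 3). With the length trend of each library removed, which was chosen after seeing the data, the median of oxidative phosphorylation shrank to 0.10, whereas those of osteoblast genes, extracellular matrix and neutrophil markers became 0.62, 0.45 and -0.50. Mean log2 CPM of the matrix list was 8.13, 9.22 and 7.74 in the controls and 9.15, 8.93 and 8.28 in the hypergravity libraries, so it varied within groups. Vcam1, an adhesion gene of marrow stroma, fell from 406.5 ± 77.8 to 230.1 ± 36.3 CPM (-0.85, adjusted p = 0.0149), Mertk from 156.2 ± 11.6 to 119.0 ± 1.5 CPM (-0.43, 0.0368) and the mast cell gene Ms4a2 by 2.10 (-2.10, 0.0357), while their lists, marrow stromal (adjusted p = 0.798), macrophage (0.16) and mast cell and basophil markers (0.0784), were not called. NF-kB inflammatory genes were not called either (median -0.16, adjusted p = 0.714, 0 of 13 members), nor were B cell (0.474), T and NK cell (0.995), endothelial (0.836) and megakaryocyte markers (0.139), osteoclast genes (0.899, 0 of 22) or the other 15 lists tested.

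After 3 weeks edgeR called no BMSC gene, with 800 genes at an unadjusted p below 0.05 where chance gives 764, a smallest adjusted p of 0.899 and 1 gene called by DESeq2. The 5 genes with the smallest p, which did not pass, were Igkv12-44 (0 against 1.58 CPM, at least 18.91-fold), Gm7336 (1.36), Gm7665 (-0.74), Sfrp4, an inhibitor of Wnt signalling (5.64 ± 0.08 and 18.6 ± 5.6 CPM; 1.65), and Mid1 (1.14). Stromal genes had higher values under hypergravity that did not pass: Col1a1 670 ± 174 and 1806 ± 912 CPM (log2 1.36 ± 0.47), Col3a1 186.1 ± 14.4 and 724.3 ± 471.7, Cxcl12 154.4 ± 11.1 and 531.4 ± 273.0, and Alpl 9.98 ± 0.78 and 36.1 ± 22.8 CPM (1.78 ± 0.40). The matrix list averaged 7.48 and 7.15 on the log2 CPM scale in controls and 8.998 and 7.84 in hypergravity libraries. UPR genes lay within 0.18 of 0 on the log2 scale, with Hspa5 at 1131 ± 0.18 and 1173 ± 14.8 CPM.

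As lists, extracellular matrix (median 1.20; camera adjusted p = 1.65e-08; 11 of 20 higher adjusted over the list alone) and osteoblast genes (1.19; 9.74e-05; 1 of 13) were higher in the 3 week BMSC set, each with adjusted p = 0.8 with an estimated correlation. Actin cytoskeleton and YAP targets (0.84; 0.000431), ATF4 and CHOP targets (0.46; 0.00403) and clock genes (0.29; 0.00519) were higher with adjusted p = 0.842, 0.803 and 0.8 with an estimated correlation. Interferon-stimulated genes (-0.45; 0.000219), lysosomal genes (-0.22; 0.00288) and oxidative phosphorylation (-0.14; 0.044, with Cycs higher adjusted over the list alone) were lower, with adjusted p = 0.871, 0.917 and 0.94 with an estimated correlation. Without hypergravity replicate 1 the calls of actin and YAP targets (adjusted p = 0.518), ATF4 and CHOP targets (0.146), clock (0.115), lysosomal (0.0942) and oxidative phosphorylation genes (0.674) ended, and that of interferon-stimulated genes ended without control replicate 2 (0.153). The other 23 lists tested were not called.

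Over both BMSC sets edgeR called no gene, with 2243 at an unadjusted p below 0.05, a smallest adjusted p of 0.162 and 285 calls by DESeq2; without control 1 week replicate 2 it called 176 and without hypergravity 1 week replicate 1 it called 1. Tmem245, Kcnj10, Hipk2, Ddi2 and Kat6a had the smallest p. Osteoblast genes (median 1.10; camera adjusted p = 6.69e-05; 5 of 13 higher adjusted over the list alone), extracellular matrix (0.85; 6.63e-07; 11 of 20) and ATF4 and CHOP targets (0.42; 7.09e-06; 2 of 23 higher, 1 lower) were higher. So were actin and YAP targets (0.72; 0.00597; 8 higher and 1 lower of 17) and clock genes (0.13; 0.0227; 2 of 10). Interferon-stimulated (-0.41; 0.00142), lysosomal (-0.12; 0.0345) and macrophage genes (-0.15; 0.0469; 1 of 16) were lower. Calls ended for actin and YAP targets without hypergravity 3 week replicate 1 (adjusted p = 0.21), for macrophage (0.236), lysosomal (0.366) and clock genes (0.139) without control 1 week replicate 3 and for interferon-stimulated genes without control 3 week replicate 2 (0.0506). The smallest of these lists' adjusted p-values with an estimated correlation was 0.8. The responses of the BMSC sets differed for no gene (smallest adjusted p = 0.254, 1423 genes at an unadjusted p below 0.05, 103 by DESeq2), with Ddi2, Wdfy3, Rpl36a-ps2, Ago2 (1.36) and LOC108168974 at the smallest p.

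Finally the responses of both cell types were compared, as BMDM minus BMSC. At 1 week the responses differed for Saa3 by 12.84 ± 0.48 (edgeR adjusted p = 6.1e-12), for Il1b by 9.87 (1.75e-10) and for Cxcl2 by 9.61 (8.52e-12). No list was tested on this difference. Acp5 (2.90 ± 0.23, adjusted p = 2.55e-08), Ern1 (2.60, 5.71e-05), Atf4 (1.52, 4.43e-07), Hspa5 (1.02, 7.48e-06) and Dcstamp (-2.29, 0.000395) differed as well, and Ddit3 did not pass (0.41, 0.0763). EdgeR called 7710 of 15550 genes at 1 week, 3864 higher and 3846 lower in BMDM (50.1% higher, 33.2% with scaling by library size alone). At 3 weeks it called 39, of which 38 were higher, including Saa3 (7.42, 7.78e-07), Cxcl2 (6.68, 2.23e-07) and Il1b (6.03, 1.78e-05), whereas Acp5 (0.46), Hspa5 (0.12) and Atf4 (-0.05) had an adjusted p of 1. The higher share was 74.7% of 75 calls by DESeq2 and 32.5% of 342 with no count filter (111 higher, 231 lower). The 3 week count was 22 without BMDM control replicate 2, 25 without BMDM control replicate 1 or BMDM hypergravity replicate 1, and 24 without BMSC control replicate 2.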

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

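The tests of explanations in this part were chosen only after the results were seen; the regrouping of libraries was planned before. The results listed here stood out because a tested difference between sets or cell types was called. The responses of the BMDM sets differed for 6008 genes, and those of the cell types for 7710 genes at 1 week and 39 at 3 weeks. In BMDM the 3 week minus 1 week difference in log2 change was -4.95 for Saa3, -6.24 for Ptgs2 and -3.28 for Cxcl2. Among osteoclast genes it was -2.75 for Acp5, 2.82 for Dcstamp, 1.06 for Nfatc1, 0.92 for Tnfrsf11a, -1.66 for Mmp9 and -0.44 for Ctsk. Among UPR genes it was -0.97 for Hspa5, -1.84 for Atf4, -1.03 for Ddit3, -1.85 for Ern1 and 0.87 for Eif2ak3.

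The first pattern was the strong inflammatory change in 1 week BMDM and its smaller counterpart at 3 weeks. A few genes taking most of the counts were argued against, since the share of the 10 most abundant genes could shift the others by at most 0.087 on the log2 scale, against a lowest change of 3.15 among NF-kB members. Scaling by library size alone moved the share called higher from 49.7% to 34.7%, so the balance of rises and falls depends on scaling. RNA of the 1 week hypergravity libraries carried into the 3 week hypergravity libraries was argued against as the whole cause. With the median ratio of 4.24%, 34 of the 59 genes (57.6%) differed by over 2 SE of the 3 week change from the fold it predicts. The ratio ran from 1.1% at its 10th to 11.25% at its 90th percentile. Fitted and predicted folds were not computed alike near 0, so the count of 34 is approximate. Il6, for example, counted as above its prediction (10.65 against 8.25) although its ratio of 2.5% was below the median. A stimulus that reached the 1 week hypergravity BMDM cultures and no BMSC cultures cannot be told apart from hypergravity, because all libraries of that group could share it. The NF-kB list had a median of -0.163 in 1 week BMSC, with 0 of 13 members called, against 8.90 for the same members in BMDM. The BMSC libraries also carried macrophage transcripts, with Lyz2 at 20050 CPM (18430 in BMDM) and Csf1r at 1231 CPM (2194 in BMDM). The missing rise is therefore not one of stromal cells alone. An effect of hypergravity on the macrophage precursors stays open and untested.

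The second pattern was the fall of long genes and rise of short genes in 1 week BMSC. A trend on GC content was argued against, since removing it left 461 called genes, 357 of the 416 among them. A trend on exonic length that differs between libraries cannot be told apart from hypergravity. Removing it left 37 called genes, 36 of the 416. The median absolute log2 change of the 416 went from 0.582 to 0.369, and 414 of them kept their direction. Removal takes a length pattern away whatever gave rise to it, so these values decide nothing about its origin. Length correlations ran from 0.08 to 0.47 in controls and from -0.295 to 0.087 under hypergravity. They also differed within other arms, from -0.381 to 0.31 in 1 week BMDM controls and with 0.051 and -0.314 in 3 week BMSC hypergravity libraries. They were close in 3 week BMSC controls (-0.24 and -0.246) and in 3 week BMDM (0.026 to 0.099). Whether RNA handling or hypergravity gave rise to the trend in 1 week BMSC stays open.

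The third pattern was the spread of matrix genes among BMSC libraries of the same group. A share of stromal cells that differs between libraries had the values it needs, since matrix and stromal list scores, as deviations from group means, correlated with r = 0.941 over 10 libraries (exact permutation p = 0.0069, the smallest that 144 permutations can give; rho = 0.964, p = 0.0069). It was 0.885 without the 2 farthest libraries and 0.977 in the 6 libraries of the 1 week set, and BH-adjusted p was 0.0276 in a family of 4 relations. The other relations were r = 0.84 for endothelial (permutation adjusted p = 0.0556), 0.658 for neutrophil (0.0925) and -0.548 for macrophage markers (0.1944). Their rho were 0.818, 0.745 and -0.564, with permutation adjusted p = 0.0741, 0.0741 and 0.1875. Matrix and stromal lists both hold genes of stromal cells, which could also vary together within the cells, so r does not single out a share of cells. No biological explanation was tested for a spread within groups.

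Libraries were also regrouped within each set. In 1 week BMSC, 2 of 10 splits had as many calls as the real grouping, which gave 416 against 1011 for the highest other, and 10 splits are too few. That other split set control replicates 1 and 3 with hypergravity replicate 3, the 3 libraries with the lowest matrix scores. Over both BMDM sets 1 of 60 splits, the real grouping, reached 6307 calls, and the highest other, with 6158, kept the 1 week hypergravity libraries together. Over both BMSC sets the real grouping called 0 genes, so all 60 of 60 splits had as many by construction and their count decides nothing. The highest other, with 1150, set the same 3 libraries of the 1 week set with both 3 week controls. It thus kept the 3 week arms apart and joined the libraries with the lowest matrix scores of each set. What structure of the samples lies behind it was not tested.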

How the results depend on the processing

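Scaling by library size alone, removal of length or GC trends and the matrix covariate were chosen after seeing the data. No named gene that was called in either fit changed direction, and no called list was called the other way by fry or with the replicate block. Sign changes of genes called in neither fit were not counted. List values with an estimated correlation or without a library took the main direction, so they could not reverse in this count. With no count filter 231 of the genes differing between cell types at 3 weeks were lower and 111 higher, against 1 and 38. Of the named genes and called lists under the alternatives, 7593 values kept their side of the threshold, 58 gained a call and 448 lost it. Requiring an absolute log2 change of at least 1 left 4421 genes in 1 week BMDM, 1877 over both BMDM sets, 3642 differing between BMDM sets, 55 in 1 week BMSC and 4670 differing between cell types at 1 week, by construction. With no count filter edgeR called 205 genes in 3 week BMDM, 1313 in 1 week BMSC, 592 in 3 week BMSC, 1252 over both BMSC sets, 391 differing between BMSC sets and 342 between cell types at 3 weeks. DESeq2 called 95 in 3 week BMDM, 884 in 1 week BMSC, 1 in 3 week BMSC, 285 over both BMSC sets, 103 differing between BMSC sets and 75 between cell types at 3 weeks. Fits of only the groups compared called 139 in 3 week BMDM and 0 in 1 week BMSC, and the fit of all 19 libraries called 2 in 1 week BMSC. There the length correction left 37 and the matrix covariate gave 2493. The cause of these changes was not tested.

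Whether equal replicate numbers pair the samples was not settled. The correlation of same-numbered deviations was 0.571 and -0.403 in 1 week BMDM and -0.293 in 3 week BMDM. It was -0.133, 0.227 and 0.651 in 1 week BMSC and 0.255 in 3 week BMSC. In an arm of 2 libraries the deviations mirror each other, so the values from such arms cannot exclude pairing. Not every 1 week BMSC library correlated best with its own number. With the number as a block, edgeR called 9506 genes in 1 week BMDM, 183 in 3 week BMDM (147 higher, 36 lower), 7911 over both, 7646 differing between sets, 657 in 1 week BMSC (97 higher, 560 lower) and 8376 and 52 differing between cell types at 1 and 3 weeks. The other BMSC gene counts stayed at 0 under the block. List calls ended under it for heat shock (adjusted p = 0.0745) and immediate early genes (0.0778) in 1 week BMDM, macrophage markers (0.175) and sex-linked genes (0.0581) in 3 week BMDM, and extracellular matrix (0.089) and heat shock genes (0.0679) over both BMDM sets.

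Leaving out each library gave 6828 to 9518 genes in 1 week BMDM, 35 to 50 in 3 week BMDM, 4948 to 7945 over both BMDM sets and 4594 to 7705 differing between them. It gave 0 to 1109 in 1 week BMSC, 0 in 3 week BMSC, 0 to 176 over both BMSC sets, 0 differing between them, and 6190 to 8226 and 22 to 34 differing between cell types at 1 and 3 weeks. A lone library left in a group was assumed to vary like the other groups.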

Other observations

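The comparison in this part was chosen after seeing the data. Controls of the 3 week set were compared with those of the 1 week set, which differ in set and possibly in duration, so the cause is open. In BMSC all 18 interferon-stimulated genes were higher in the 3 week controls (camera adjusted p = 9.05e-20, and adjusted p = 0.568 with an estimated correlation), with edgeR log2 changes of 3.76 ± 0.38 for Irf7 (adjusted p = 0.000749), 3.24 for Ifit3 and 2.78 for Isg15. Cholesterol synthesis genes were lower in 16 of 19 cases (adjusted p = 1.31e-15, and 0.569 with an estimated correlation), among them Sqle at -1.21. Macrophage markers (6 of 16 called, adjusted p = 7.53e-05, and 0.725 with an estimated correlation) and NF-kB inflammatory genes (4 of 13, 0.0352, and 0.568) were also higher. Extracellular matrix (median -1.14, 4 of 20 called, adjusted p = 0.000425, and 0.839 with an estimated correlation) and endothelial markers (-1.41, 2 of 7, 0.00279, and 0.817) were lower. EdgeR called 1078 BMSC genes between the control groups, 507 higher and 571 lower.

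In BMDM, neutrophil markers were lower in the 3 week controls in 10 of 11 cases (camera adjusted p = 1.17e-13, and adjusted p = 0.562 with an estimated correlation), with S100a9 at -3.27 ± 0.42 (edgeR adjusted p = 0.00365), Ltf at -3.69 and Ngp at -3.48. Interferon-stimulated genes were lower in 11 of 18 cases (adjusted p = 1.04e-11, and 0.725 with an estimated correlation), Ifit3 at -1.48. Mast cell and basophil markers (median -3.69, 2 of 4 called, adjusted p = 2.72e-05, and 0.369 with an estimated correlation) and class II and dendritic cell genes (-1.68, 4 of 8, 0.00136, and 0.725) were lower, with 3 of the latter 8 in the depleted part of chromosome 17. Proliferation genes (0.28, 0 of 21, adjusted p = 7.12e-05, and 0.828 with an estimated correlation) and ATF4 and CHOP targets (0.30, 5 of 23, 0.00891, and 0.725) were higher. EdgeR called 549 BMDM genes, 215 higher and 334 lower. The haemoglobin gene Hbb-bs, chosen after its values were seen, stood at 5.45 and 5.96 CPM in the 3 week controls of BMDM and at 4.96 and 4.66 CPM in those of BMSC. In the 1 week controls it was at 0 in all 3 BMSC libraries and in 2 BMDM libraries, and at 0.0504 CPM in the other BMDM library. Hypergravity libraries followed their set. Those of 3 weeks had 5.77 and 5.64 CPM in BMDM and 6.01 and 6.02 CPM in BMSC. Those of 1 week had at most 0.0501 CPM in BMDM and 0.173 CPM in BMSC. The difference thus separates the sets in both arms.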
